A study of Glycine max with 14 samples.

How the data were processed

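RNA was measured by sequencing in cotyledons of germinating soybean (Glycine max, cultivar Williams), the storage leaves of the embryo that feed the seedling and then turn green. Per the labels' protocols, plants were grown in a greenhouse, total RNA was extracted from lyophilized tissue with phenol:chloroform and lithium chloride, and libraries were made by the standard protocols of the maker and sequenced on an Illumina HiSeq instrument. The labels place the 14 libraries in 7 stages of 2 biological replicates each. Stage 1 was taken 1 day after imbibition, stage 2 at 2 days after planting, stage 3 at 2 to 3 days, stage 4 at 3 to 4 days, stage 5 at 4 to 5 days, stage 6 at 5 to 6 days and stage 7 at 6 to 7 days. How many seedlings made up a replicate, and whether a library was prepared as stranded, is not given in the sources used here.

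The deposited files hold one RPKM value per gene model and library (reads scaled by model length and by the library's read total), per the file headers, for 78773 models of 69145 gene loci. Reads were aligned with Bowtie, per the submitters' processing notes. Its version and settings, the genome build, the annotation, the counting of reads and the treatment of reads that match several models are not given in the sources used here. The identifiers are numbered by chromosome in an older soybean style, and the files pair none of them with a gene name. The RefSeq gene table at hand (assembly Glycine_max_v4.0, 59048 genes) matched 0 of the identifiers, so no coordinates are given, and lists chosen by gene description, the glyoxylate cycle and transcription factor families of the series title among them, were not analysed here.

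In place of those, 11 lists of 56 identifiers, fixed before the data were examined from general knowledge of published soybean identifiers, were used: glycinins, beta-conglycinins, seed lipoxygenases, vegetative lipoxygenases, seed lectin and Kunitz trypsin inhibitors, the P34 seed thiol protease, Rubisco small subunits, fatty acid desaturases, chalcone and isoflavone synthases, the embryo regulators LEC1 and ABI3, and phytochromes A and B. No table used here pairs these identifiers with those names, so each list name is an assumption about its members. As a partial check, 53 of the 56 identifiers carry the number of a chromosome on which the RefSeq table holds a symbol of the same family. Other models are given by identifier alone, with no name. By the rule fixed beforehand for data without names, each contrast names the 2 largest rises and the 2 largest falls, taking 1 model per locus, the one with the highest mean, among models past the test with a mean of at least 10 RPKM in the higher stage.

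The read total behind each library's RPKM values was recovered from the values. Each RPKM value is a whole multiple of the value of 1 read, and all of the 67016 models with a value above 0 in at least 2 libraries (100%) gave whole reads within 0.003 reads (or 1e-08 of the read number) in every library. The recovered reads sum to between 99.99% and 100% of the total in each RPKM denominator, so the values are relative to all read assignments to models. A read that matches several models may be counted more than once, so the totals need not equal the reads sequenced. Those totals run from 83.9 M to 131 M reads per library (M, reads in units of 1e+06), and at this depth 1 RPKM on a model of the median tested length (1404 bases) is worth well over the floor of 3 reads. Of the tested models, 76 (0.171%) had the same reads in all 14 libraries as a model at another locus. Since the counting of reads that match several models is not given, values of near-identical copies are uncertain.

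Values were transformed as log2(RPKM + 1), and models with at least 1 RPKM in at least 2 libraries were tested (44450 models of 35547 loci). A log2 fold change is on that scale, which understates the change of low models. All 14 libraries were fitted together in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean per stage, no replicate term and 7 residual degrees of freedom, with empirical Bayes moderation using a mean-variance trend and robust estimation. Residual spread is pooled over the stages, so the wider stage 1 pair also enters the error of contrasts without stage 1. For contrasts with stage 1 the pooled error can be too small. P-values are two-sided and Benjamini-Hochberg adjusted within each contrast. A model counts as changed at an adjusted p under 0.05 and, for a contrast of 2 stages, an absolute log2 fold change of at least 1. The moderated F test over the stages used the adjusted p alone. Counts of list members in a contrast, over all models or over the list alone, also used the adjusted p alone. Adjustment over the list alone does not cover the number of lists or of contrasts. For the P34 list, with 1 model, it leaves the p-value unadjusted. Counts of list members under an alternative setting used the fold threshold as well. Lists with at least 3 tested members were tested for stage 7 against stage 1 with limma's camera at a preset correlation of 0.01, adjusted over the 9 such lists, with an estimated correlation and with fry beside it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

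The procedure was tested on simulated data for stage 7 against stage 1, with 44450 models of which 200 were changed. By the adjusted p alone, it called 0% of the models changed by a fold of 2, 25.4% by a fold of 4 and 48.5% by a fold of 8. There was 1 false call among 50 calls. With the fold threshold as well, there were 0 calls in a contrast without change. In that setting the test missed many true changes of these sizes. With only 200 changed models the adjusted threshold is stricter than in the deposited data. There, 19873 models were at a limma adjusted p under 0.05 for this contrast. The shares therefore do not give the power of the test in the deposited data. The absence of a call is not evidence of an equal level. In the same simulation camera called the changed list, which held only models raised by a fold of 8, and it also called 2 of 50 random lists at an unadjusted threshold of 0.05. Simulated models were drawn independently. In the lists tested here the estimated correlation ran from -0.047 (seed lectin and Kunitz trypsin inhibitors) to 0.985 (Rubisco small subunits). The simulation therefore does not give the rate of false list calls where members are correlated.

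Alternatives fixed before the data were examined were a pseudocount of 0.1 or 5, no filter, a filter of 5 RPKM in 2 libraries, quantile normalization, upper quartile scaling, moderation without trend and robust estimation, 1 model per locus, replicate number as a block, a fit of only the 4 libraries compared, no fold threshold, each library left out in turn and, for the lists, an estimated correlation. Chosen after seeing the data were limma voom on the recovered reads, and RPKM rescaled to the reads outside a block of models on chromosome 13 that took more of the replicate 2 libraries. Scaling moves the log2 changes of all tested models. Its size is given here as the median, over models, of the shift of each model's log2 change. Stage 2 minus stage 1 has a median log2 change of 0.24 as deposited. The median shift was -0.30 under quantile normalization and -0.13 under upper quartile scaling. For stage 5 minus stage 4 the median is -0.18 and the shifts are 0.14 and 0.13, for stage 6 minus stage 5 they are -0.27, 0.30 and 0.27, for stage 7 minus stage 6 they are 0.21, -0.26 and -0.25, and for stage 7 minus stage 1 they are -0.12, -0.083 and 0.13. Rescaling without the chromosome 13 block gave a median shift of -0.089 for stage 7 minus stage 1.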

Results

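Cotyledon RNA was profiled over 7 stages of germination and seedling growth in the soybean cultivar Williams, from 1 day after imbibition (stage 1) to 6 to 7 days after planting (stage 7), in 2 biological replicates per stage. The title of the series places the interest in the passage of the cotyledon from a storage organ to the first working leaf. Each library held between 83.9 M (stage 7 replicate 1) and 131 M (stage 5 replicate 1) read assignments to gene models, recovered from the RPKM values. Between 32209 (stage 1 replicate 1) and 39866 (stage 4 replicate 1) of the 78773 models reached 1 RPKM, and 9655 models were at 0 in all 14 libraries. The 10 highest models took a mean of 4.37% of all RPKM at stage 3 and 14.2% at stage 6.

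The libraries lined up by stage along the first principal component, which held 57.5% of the variance over the 44450 tested models, from stage 1 to stage 6, and stage 7 lay back from stage 6 on it. The correlation of mean log2 values with stage 1, across models, was 0.908 at stage 2, 0.679 at stage 4, 0.497 at stage 6 and 0.569 at stage 7. Models are not independent replicates, so these correlations describe the libraries. The replicates of stage 1 stood apart from each other. They correlated at 0.803 across models and 14197 models (31.9%) differed at least 2-fold between them, against 0.945 to 0.963 and 1541 to 2997 models at the other stages. A run of 52 models with identifiers from Glyma13g11810 to Glyma13g12210 took 0.566% to 3.43% of reads in the replicate 1 libraries and 3.43% to 15.3% in the replicate 2 libraries, and it was 4.45 to 13.8 times higher in replicate 2 in each of the 7 stages.

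**Figure D1:**
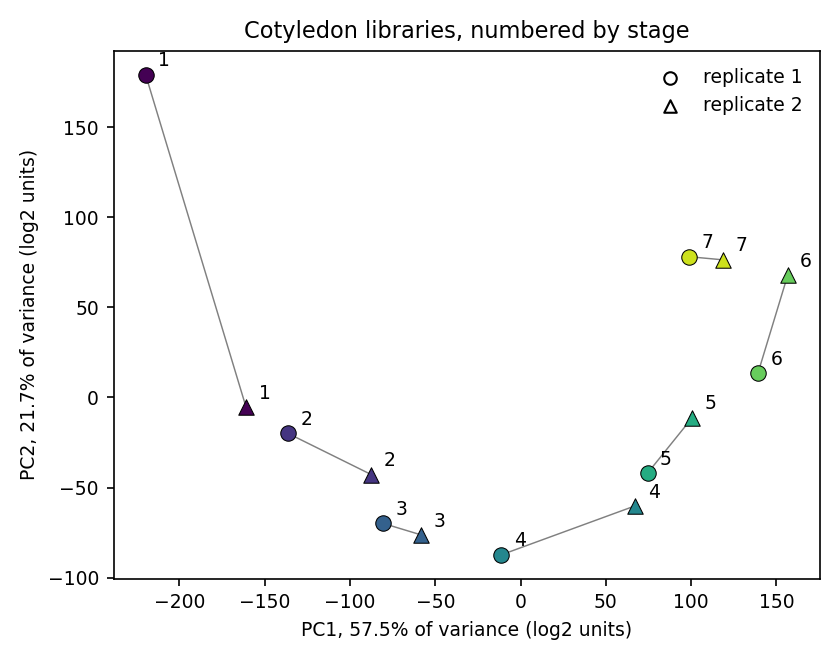
First 2 principal components of log2(RPKM + 1) over the 44450 tested models, with the share of variance on each axis. Points are libraries numbered by stage, circles replicate 1 and triangles replicate 2, and grey lines join replicates. PC1 (57.5%) runs from stage 1 to stage 6 with stage 7 behind stage 6, and the stage 1 replicates lie far apart on PC2 (21.7%).

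**Figure D2:**
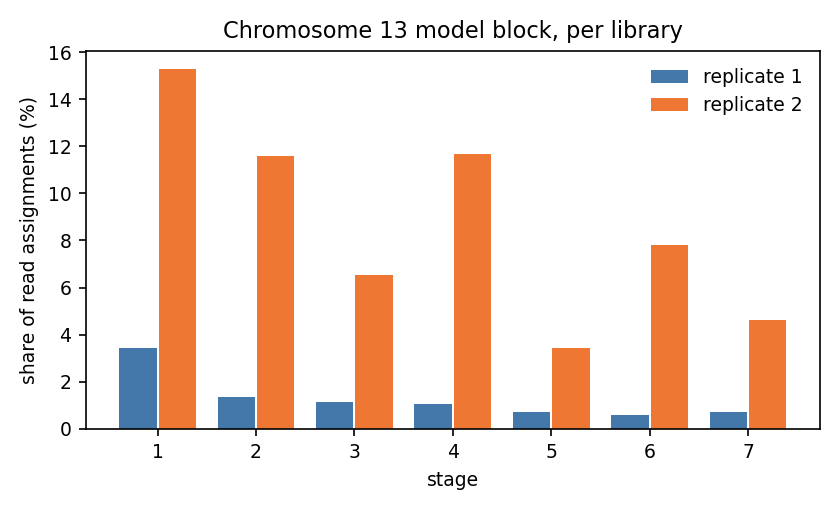
Share of all read assignments taken by the block of 52 chromosome 13 models in each library, with bars for replicate 1 (blue) and replicate 2 (orange) at each stage. The replicate 2 bar is the higher one at each of the 7 stages, by 4.45 to 13.8 times.

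Many expressed models changed over the time course. The moderated F test in limma called 25762 of 44450 models (58.0%), from 20661 loci, and between 20188 and 36129 models with 1 library left out. Of these, 24018 also spanned at least 1 log2 unit between their highest and lowest stage means, and their peaks and troughs were unevenly spread. The mean was highest at stage 1 in 7495 of them (31.2%), at stage 7 in 4212 (17.5%), at stage 4 in 3533 (14.7%) and at stage 3 in 2977 (12.4%). It was lowest at stage 6 in 10344 (43.1%), at stage 1 in 8816 (36.7%) and at stage 7 in 2897 (12.1%). The peak and trough of a model are read from stage means of 2 libraries, as deposited, and were not tested one by one. The median log2 change of all tested models was -0.27 from stage 5 to stage 6 and 0.21 from stage 6 to stage 7. Under quantile normalization these medians were 0.0035 and -0.019. How far the share of troughs at stage 6 depends on the scaling was not tested.

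From stage 1 to stage 7, the 3 Rubisco small subunit models, for the nuclear-encoded part of the enzyme that fixes carbon dioxide, all rose, with log2 fold changes of 8.37 to 8.50. The highest of them went from 32.6 ± 18.5 RPKM at stage 1 (SD, n = 2) to 16900 ± 1173 at stage 6 and 11240 ± 1158 at stage 7, and the lowest from 16.9 ± 10.9 to 5384 ± 599 at stage 7. All 5 glycinin models fell, with log2 fold changes of -5.55 to -3.08, and all 5 beta-conglycinin models fell, with log2 fold changes of -4.00 to -1.33. With a pseudocount of 5, all 5 beta-conglycinins kept a limma adjusted p under 0.05 and 2 of them met the fold threshold. In a fit of only the 4 libraries compared, 3 of 5 passed. Glycinins and beta-conglycinins are the main storage globulins of the seed. The glycinin highest at stage 1 went from 112 ± 8.51 to 1.42 ± 0.138 RPKM, and the highest beta-conglycinin from 78.6 ± 34.9 to 3.91 ± 1.78. The 3 seed lipoxygenase models fell too. With a pseudocount of 5 all 3 kept a limma adjusted p under 0.05 and 2 met the fold threshold, and 2 of 3 passed in the fit of only 4 libraries. The most abundant seed lipoxygenase was at 171.5 ± 191 RPKM at stage 1 and 1.45 ± 0.638 at stage 7, with a spread at stage 1 as large as its mean. Among the vegetative lipoxygenases, a group of related enzymes that oxidise polyunsaturated fatty acids, 4 of the 9 identifiers were tested. Of these, 2 rose (from 2.19 ± 0.698 to 318 ± 48.2 RPKM and from 0.262 ± 0.208 to 170 ± 33.2), and the other 2 had log2 fold changes of 0.51 and 0.52 that did not pass the test. The model at 0.52 was low throughout this contrast, at 0.00799 ± 0.00145 RPKM at stage 1 and 0.469 ± 0.399 at stage 7. In limma voom its log2 fold change was 5.29 (adjusted p = 0.0373). The model at 0.51 ran from -0.011 to 1.04 with 1 library left out. The counts adjusted over the list alone were the same for each of these lists.

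By camera, 5 of the 9 tested lists passed an adjusted p of 0.05 for stage 7 against stage 1. They were Rubisco small subunits (up, adjusted p = 0.000926), glycinins (down, 0.000926), beta-conglycinins (down, 0.00446), seed lipoxygenases (down, 0.0196) and vegetative lipoxygenases (up, 0.0196). None of the 5 calls held with an estimated correlation between members, where the adjusted p was 0.228 for Rubisco small subunits and for seed lipoxygenases, 0.244 for glycinins, and 0.250 for beta-conglycinins and for vegetative lipoxygenases. The fry test, which asks whether the members move one way and sets them against no other models, gave adjusted p from 4.74e-06 to 0.00149 for the 5 lists. It did not separate them from the seed lectin and Kunitz list (fry adjusted p = 0.000334), which camera did not call. The fry adjusted p was 0.270 for desaturases, 0.268 for chalcone and isoflavone synthases and 0.780 for phytochromes. The camera call of the vegetative lipoxygenases was lost without stage 1 replicate 2 (adjusted p = 0.109), without stage 7 replicate 2 (0.0567) and with no filter (0.0789). Some members had nearly equal reads in every library, with ratios of 0.997 to 1.00 and of 1.00 to 1.06 in 2 pairs of beta-conglycinin models and of 0.982 to 0.992 in a pair of Rubisco models. How reads that match several models were counted is not given in the sources used here, so the separate values of these pairs are uncertain.

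Other lists went several ways. Of the seed lectin and Kunitz trypsin inhibitor models, 3 of 4 fell (log2 fold changes -3.42 to -2.36), the remaining one was at 5.24 ± 5.11 RPKM at stage 1 and 14.1 ± 15.3 at stage 7, and the list missed the threshold (camera adjusted p = 0.0603). The model on the list of the P34 seed thiol protease fell from 15.8 ± 9.05 to 0.445 ± 0.198 RPKM (log2 fold change -3.43, limma adjusted p = 7.05e-05). Both tested models of the LEC1 and ABI3 list, transcription factors of embryo maturation, fell, from 58.0 ± 26.3 to 1.03 ± 0.953 and from 39.4 ± 16.9 to 0.650 ± 0.653 RPKM, and the 2 others lay under the filter. Of the 7 tested fatty acid desaturase models 1 rose, 2 fell and 4 did not pass (camera adjusted p = 0.584). With a pseudocount of 5, 3 models kept a limma adjusted p under 0.05, of which 0 rose and 1 fell past the fold threshold. The list median log2 fold change was -0.37 with all libraries and ran from -0.99 to 0.29 with 1 library left out. Of the 9 chalcone and isoflavone synthase models, for enzymes of flavonoid synthesis, 4 fell and 5 did not pass (camera adjusted p = 0.239). Only 1 fell in a fit of the 4 libraries compared and 3 fell with no filter. Beside the 4, 1 model rose under upper quartile scaling and with the replicate block. Values moved with single libraries. Glyma01g43880.1 went from a log2 fold change of -2.43 to -1.38 without stage 1 replicate 1 and to -1.70 without stage 7 replicate 1. Glyma11g01350.2 went from -2.26 to -1.16 and to -1.52. The list median turned from -0.62 to 0.99 without stage 1 replicate 1. None of the 5 phytochrome models, for red light receptors, passed (0.722), with log2 fold changes from -0.29 to 0.59, and the values turned with the stage 1 library left out. Without replicate 2 of that stage, 4 of the 5 had log2 fold changes of 1.00 to 1.38. Without replicate 1 the list median was -0.91. The counts adjusted over the list alone were again the same.

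**Figure D3:**
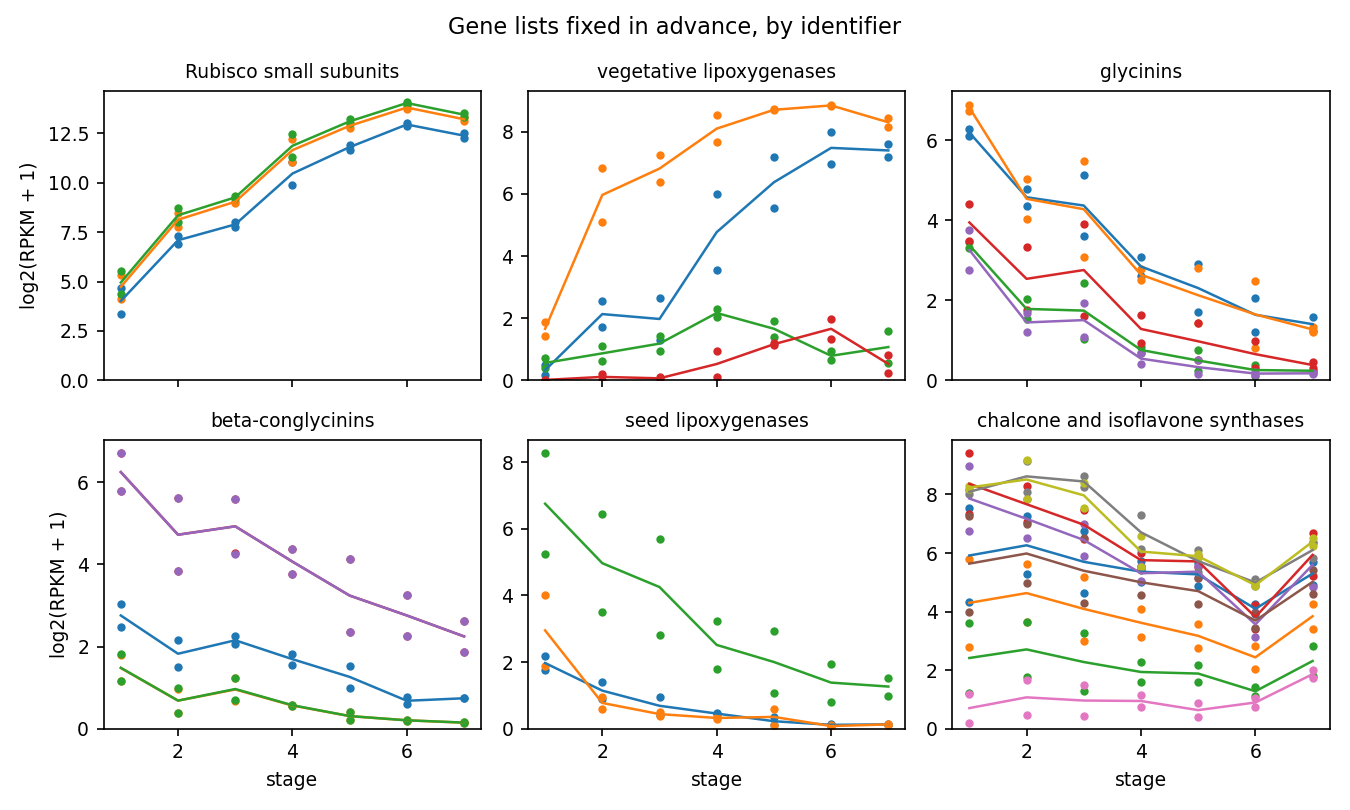
log2(RPKM + 1) of the tested members of 6 gene lists by stage. Each colour is a model, points are the 2 libraries of a stage and lines join stage means. Rubisco small subunit models peak at stage 6, where the highest reaches a mean of 16900 RPKM, and glycinin, beta-conglycinin and seed lipoxygenase models are highest at stage 1.

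Over all models, 15596 (12470 loci) changed between stage 1 and stage 7, with 8196 higher and 7400 lower at stage 7. The largest rises were Glyma18g04080.1, from 1.69 ± 0.884 to 1717 ± 478 RPKM (log2 fold change 9.33 ± 0.758 SE, limma adjusted p = 1.16e-05), and Glyma11g34230.2, from 2.50 ± 1.37 to 2005 ± 332 RPKM (9.21 ± 0.730, adjusted p = 1.04e-05). Both stayed below 100 RPKM up to stage 4 (55.3 and 97.6) and reached 633 and 1066 RPKM at stage 5. The largest falls were Glyma17g03040.1, from 273 ± 75.6 to 2.18 ± 1.51 RPKM (-6.49 ± 0.436, adjusted p = 4.59e-06), and Glyma16g03470.1, from 381 ± 362 to 3.86 ± 3.80 RPKM (-6.13 ± 1.06, adjusted p = 0.00112). Both had fallen to 36.1 and 34.7 RPKM by stage 2. Which direction held more models turned with the setting: 7533 were higher and 7817 lower under quantile normalization, 7654 and 8643 after rescaling without the chromosome 13 block, 6108 and 6135 with the filter of 5 RPKM, 9681 and 10192 with no fold threshold, and 7045 and 9389 without stage 1 replicate 1, against 9082 and 6137 under upper quartile scaling. The count fell to 8044 with a pseudocount of 5 and to 6419 (4335 higher and 2084 lower) in a fit of only the 4 libraries compared.

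Between stage 1 and stage 2 the 3 Rubisco small subunit models had already risen, with log2 fold changes of 3.08 to 3.41, and the more abundant vegetative lipoxygenase model rose from 2.19 ± 0.698 to 73.4 ± 56.8 RPKM (limma adjusted p = 0.00744). Of the 5 glycinin models 1 fell over all models tested and 4 fell when adjusted over the list alone. For beta-conglycinins these counts were 0 and 3 of 5, and for seed lipoxygenases 0 and 2 of 3. The 3 beta-conglycinins (log2 fold changes -0.93, -0.80 and -0.79) and a seed lipoxygenase (-0.83) in these counts lay below the fold threshold, which the list counts do not use. Over the list alone, 2 of 4 lectin and Kunitz models, the P34 model and both tested models of the LEC1 and ABI3 list also fell and 1 of 7 desaturases rose. None of these passed over all models. Counts over a list alone are a loose bar here, since 9886 of the 44450 tested models had an unadjusted p under 0.05 at this step. In all, 789 models changed, 625 higher and 164 lower at stage 2. The largest rises were Glyma14g31400.1, from 1.10 ± 0.868 to 74.7 ± 73.4 RPKM (log2 fold change 4.78 ± 0.736 SE, adjusted p = 0.0140), and Glyma15g03040.2, from 2.28 ± 1.66 to 115 ± 123 RPKM (4.66 ± 0.810, adjusted p = 0.0219), both with a spread at stage 2 about as large as the mean. The largest falls were Glyma02g03420.1, from 33.9 ± 6.73 to 0.920 ± 0.862 RPKM (-4.25 ± 0.298, adjusted p = 0.000986), and Glyma08g18400.1, from 55.2 ± 28.5 to 3.55 ± 2.19 RPKM (-3.61 ± 0.489, adjusted p = 0.00962). The count depended on single libraries, with 138 calls without stage 1 replicate 1, 14177 without stage 1 replicate 2, 298 without stage 2 replicate 1, 9 without stage 2 replicate 2, between 366 and 472 without any other library, and 0 in a fit of only the 4 libraries compared. The split of 625 higher and 164 lower became 399 and 304 under quantile normalization, 297 and 140 under upper quartile scaling and 349 and 175 after rescaling without the chromosome 13 block. It was 70 and 68 without stage 1 replicate 1, and 2 and 7 without stage 2 replicate 2.

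The 4 steps between stage 2 and stage 6 gave few calls in this fit, which has no replicate term. Its residual spread is pooled over all stages, the wide stage 1 pair included. The SD of the replicate log2 difference was 1.10 at stage 1 and 0.437 to 0.531 at the other stages. The few calls are therefore no measure of how little changed at these steps. With replicate number as a block, the step from stage 3 to stage 4 gave 295 calls, 265 higher and 30 lower at stage 4. That fit gave 51 calls from stage 4 to stage 5, and 0 from stage 2 to stage 3 and from stage 5 to stage 6. From stage 3 to stage 4, Rubisco small subunit models had log2 fold changes of 2.58 to 2.61, which passed when adjusted over the list alone (3 of 3) and not over all models tested. Adjusted over the list alone, 3 of 5 glycinins and both tested models of the LEC1 and ABI3 list fell and 3 of 4 vegetative lipoxygenases rose at that step, again with none past the test over all models. Glycinins at -0.985 and -0.964 and a vegetative lipoxygenase at 0.986 in these counts lay below the fold threshold. At the same step and over the list alone, 1 of 4 lectin and Kunitz models and 2 of 9 chalcone and isoflavone synthases fell. There 1 of 7 desaturases rose. From stage 2 to stage 3 both tested models of the LEC1 and ABI3 list fell over the list alone (log2 fold changes -2.00 and -1.95). From stage 4 to stage 5 the 3 Rubisco models rose over the list alone (1.23 to 1.34). No other list member passed over its list at the steps from stage 2 to stage 6. From stage 2 to stage 3, limma called 0 models (672 at an unadjusted p under 0.05). From stage 5 to stage 6 it called 0 (5452 at an unadjusted p under 0.05). Limma voom on the recovered reads called 0 at both steps. The latter step gave 30 calls under quantile normalization, 13 under upper quartile scaling and 8 with a pseudocount of 5. All were higher at stage 6 in these settings, but most were lower without stage 5 replicate 1. From stage 3 to stage 4 the 1 call was Glyma12g29090.1, from 3.61 ± 0.947 to 49.8 ± 20.6 RPKM (log2 fold change 3.42 ± 0.350 SE, adjusted p = 0.0498), and 5630 models had an unadjusted p under 0.05. From stage 4 to stage 5, 26 models rose and 1 fell. The largest rises were Glyma13g40820.1, from 0.598 ± 0.528 to 21.4 ± 5.11 RPKM (3.83 ± 0.499, adjusted p = 0.0478), and Glyma03g12070.1, from 0.857 ± 0.748 to 21.5 ± 5.36 RPKM (3.64 ± 0.388, adjusted p = 0.0182). The fall was Glyma05g28530.1, from 35.5 ± 4.16 to 7.55 ± 0.359 RPKM (-2.09 ± 0.294, adjusted p = 0.0478). The calls at both of these steps ended in a fit with no filter and in limma voom, and single libraries moved all 4 counts. From stage 2 to stage 3 there were 38 calls without stage 3 replicate 2 and 2 without either stage 1 library, and from stage 5 to stage 6 there were 35 without stage 5 replicate 1 and 3 without either stage 4 library. From stage 3 to stage 4 there were 332 without stage 4 replicate 1, 204 and 222 without replicate 1 or replicate 2 of stage 1, 106 without stage 3 replicate 2 and 0 without any other library. From stage 4 to stage 5 there were 138 without stage 4 replicate 2, 86 without stage 5 replicate 1, 46 and 44 without replicate 1 or replicate 2 of stage 1, 13 and 10 without replicate 1 or replicate 2 of stage 6, and 0 without any library of stages 2 and 3, stage 4 replicate 1 or stage 5 replicate 2.

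From stage 6 to stage 7, 458 models changed, 405 higher and 53 lower at stage 7. Of the 405, 365 had their highest stage mean at stage 7, and in 344 both stage 7 libraries lay above all 12 others. The largest rises were Glyma15g18360.1, from 1.92 ± 2.31 to 223 ± 171 RPKM (log2 fold change 6.29 ± 0.775 SE, limma adjusted p = 0.00704), and Glyma19g41090.1, from 6.94 ± 8.78 to 418 ± 373 RPKM (6.04 ± 1.08, adjusted p = 0.0318). The largest falls were Glyma12g16380.2, from 51.8 ± 1.09 to 4.11 ± 3.70 RPKM (-3.59 ± 0.556, adjusted p = 0.0175), and Glyma06g42080.1, from 25.0 ± 0.938 to 2.24 ± 1.45 RPKM (-3.08 ± 0.397, adjusted p = 0.00794), which both had their highest means at stage 5 (99.9 and 43.0 RPKM). No list member passed over all models, and 1 of 4 vegetative lipoxygenases fell when adjusted over the list alone. The Rubisco models had log2 fold changes of -0.59 to -0.57 and the 9 chalcone and isoflavone synthase models 0.97 to 2.12. The calls ended with a pseudocount of 0.1, in limma voom and in a fit of only the 4 libraries compared (0 each), fell to 25 without stage 6 replicate 1, to 93 without stage 7 replicate 1 and to between 190 and 262 without any library of stages 2 to 5, and rose to 702 without stage 7 replicate 2 and to 1713 and 1715 without replicate 1 or replicate 2 of stage 1. They numbered 8 with the filter of 5 RPKM. The split of 405 higher and 53 lower became 167 and 143 under quantile normalization and 165 and 85 under upper quartile scaling.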

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

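The cause of these moves was not tested unless a fit with fewer models or libraries shows it. The voom fit and the rescaling without the chromosome 13 block were chosen after seeing the data. The F test count (25762) stayed within 1.5 times in every alternative run, from 20188 to 36129 with 1 library left out. Stage 7 against stage 1 (15596) gave 11838 to 19226 with 1 library left out, 8044 with a pseudocount of 5 and 6419 in the fit of 4 libraries.

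Stage 2 against stage 1 (789) gave 1498 and 222 with pseudocounts of 0.1 and 5, 486 with no filter, 437 with upper quartile scaling, 0 with 4 libraries, 1193 with voom, 524 without the chromosome 13 block, and 9 to 14177 with 1 library left out. Stage 3 against stage 2 (0) gave 0 to 38 with 1 library left out. Stage 4 against stage 3 (1) gave 14 and 0 with pseudocounts of 0.1 and 5, 82 with the filter of 5 RPKM, 47 without trend and robust estimation, 0 with no filter, quantile normalization, upper quartile scaling, 4 libraries, voom and rescaling, and 0 to 332 with 1 library left out. Stage 5 against stage 4 (27) gave 0 with a pseudocount of 0.1, no filter and voom, 4 with the filter of 5 RPKM, 11 with quantile normalization, 6 with upper quartile scaling, 4 without trend and robust estimation, 3 with 1 model per locus, 44 with 4 libraries, 5 with rescaling, and 0 to 138 with 1 library left out. Stage 6 against stage 5 (0) gave 8 with a pseudocount of 5, 30 with quantile normalization, 13 with upper quartile scaling, and 0 to 35 with 1 library left out. Stage 7 against stage 6 (458) gave 0 with a pseudocount of 0.1, 4 libraries and voom, 8 with the filter of 5 RPKM, 250 with upper quartile scaling, 291 without trend and robust estimation, and 25 to 1715 with 1 library left out. A stage left with 1 library was assumed to vary like the others.

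The labels name no shared batch or day, but their library numbers run consecutively in stage order within each replicate number. The replicate numbers thus mark 2 numbered series, and what the numbering stands for is not given in the sources used here. They were not taken as pairs, since the replicate differences of 2 stages did not correlate alike in all pairs of stages. The correlation was above 0.1 in 18 of 21 pairs. It was below 0 in the 3 pairs of stage 1 with stages 5, 6 and 7. All 15 pairs among stages 2 to 7 lay above 0.1. With the replicate block, the calls were 1419 for stage 2 against stage 1, 295 for stage 4 against stage 3, 51 for stage 5 against stage 4 and 759 for stage 7 against stage 6, and the other counts stayed within 1.5 times.

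The 5 list calls became 2 with the filter of 5 RPKM, which left 3 of them under 3 members, 0 with an estimated correlation, and 5 to 6 with 1 library left out, not always for the same lists. The vegetative lipoxygenase call was lost in 3 settings (adjusted p = 0.109, 0.0567 and 0.0789). The seed lectin and Kunitz list was gained without stage 1 replicate 2 (0.0264), stage 5 replicate 1 (0.0495), stage 5 replicate 2 (0.0493) or stage 7 replicate 2 (0.0492), and the chalcone and isoflavone synthase list without stage 1 replicate 2 (0.0234). The lists were not run with voom.

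Of the 16 models named by contrast, the 4 of stage 7 against stage 1 kept direction and call in all 26 alternatives, and the 12 others kept their direction and lost an adjusted p under 0.05 in 1 to 19. Of the 48 tested list members, 8 lost an adjusted p under 0.05 in some setting (4 chalcone and isoflavone synthases, 2 beta-conglycinins, 1 seed lipoxygenase, 1 of the lectin and Kunitz list) and 11 gained one. The log2 fold change of 15 members, none past the test with all libraries, changed sign in some setting. With 1 library left out, the 5 phytochromes ran from -0.95 to 1.00, -0.94 to 1.24, -0.19 to 1.38, -0.91 to 0.33 and -0.32 to 1.023, 4 desaturases from -0.96 to 0.85, -0.20 to 1.501, -0.99 to 0.26 and -1.05 to 0.29, 4 chalcone and isoflavone synthases from -2.22 to 0.99, -1.97 to 1.05, -1.31 to 1.11 and -2.26 to 1.01, a vegetative lipoxygenase from -0.011 to 1.04 and a lectin or Kunitz model from -0.24 to 2.35. The list medians ran from -0.91 to 1.023 for phytochromes, -0.99 to 0.29 for desaturases and -2.07 to 0.99 for chalcone and isoflavone synthases. The first desaturase was also at 0.54 with a pseudocount of 0.1, 0.053 with upper quartile scaling and 1.09 with voom, the first phytochrome at -0.001 with a pseudocount of 5, -0.08 with quantile normalization and -0.079 with rescaling, and the third of these synthases at 0.016 with upper quartile scaling.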

Other observations

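Stage 7 lay partly back towards stage 1, in a comparison chosen after the data were seen. Models were chosen from stages 1 and 5 alone, by a gap of at least 2 log2 units between all libraries of one stage and all libraries of the other, and then followed from stage 6 to stage 7, which share no library with the choice. Of the 560 models lower at stage 5 than at stage 1, 484 (86.4%) moved up from stage 6 to stage 7 by more than the median of all tested models (log2 0.21), with a median change of 0.75. Of the 2116 models higher at stage 5, 1754 (82.9%) moved by less than that median, with a median change of -0.49. Single models seldom passed the test from stage 6 to stage 7, where 14 of the 560 and 31 of the 2116 passed towards their stage 1 side and 0 and 7 passed away from it.

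The following weighs 2 patterns, and the tests of developmental lag and of depth were chosen after the result was seen. Replicates of a stage differed at least 2-fold in 1541 to 14197 models. A fixed difference between the replicate series would give replicate differences that correlate between all stages. The lowest of the 21 correlations was -0.173 (stages 1 and 6), so a fixed difference alone does not account for stage 1. The 3 correlations below 0 all included stage 1, whose libraries differed most. All 15 pairs among stages 2 to 7 lay at 0.149 to 0.602, so a fixed difference over those stages stays open. The chromosome 13 block was higher in replicate 2 at each of the 7 stages. A candidate explanation is that replicate 2 seedlings were further along. At stages 2 to 6 the replicate difference, across models, correlated with the change between the stages on either side at 0.234 to 0.652, the lowest being 0.234. Age of the seedlings, growth conditions and any other difference between the replicate series, biological or technical, stay open.

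The stage 1 libraries differed most, with 31.9% of models at least 2-fold apart. Lower depth of replicate 1 is argued against by its total of read assignments, 1.30 times that of replicate 2. A bias with model length, as RNA breakdown would give, is argued against by an absolute rank correlation of 0.0276 between the difference and length, below the highest of the other 6 stages (0.190). A less advanced replicate 1 may account for part of it, as a hypothesis, since the difference correlated at 0.574 across models with the change from stage 2 to stage 3, although at 0.329 with the change from stage 2 to stage 4. Other differences between these 2 libraries were not tested.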
